A study of Mus musculus with 384 samples.

How the data were processed

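Single-cell and control libraries were made from mouse mammary epithelial cells with Smart-seq2, and the labels give 384 samples, of which 5 are libraries of many cells 5 are negative control wells and the others are single-cell wells. The deposited table holds raw read counts per gene and well, to which the authors applied no normalization. The submitters' processing notes name cutadapt 1.13, STAR 2.5.2b, HTSeq 0.6.0, Seurat and the GRCm38 genome without giving their roles, and the annotation version is not given in the sources used here. The table has 49585 genes and 92 spike-in sequences, which held 11 reads in all wells together and were not used. Gene symbols and coordinates come from GENCODE M21 on GRCm38, in which 49326 of the gene identifiers were found.

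Samples were grouped by condition and sorted cell type as the labels give them. The labels do not say which animal a cell came from, how the hybrid gate was drawn or how many cells the libraries of many cells hold. A single-cell well was kept with at least 100000 reads in genes, at least 1000 genes and at most 20% mitochondrial reads. Of the 55 wells left out, 47 had too few reads, 8 had too large a mitochondrial share and 0 had enough reads but too few genes. No caller of wells with more than 1 cell was run, and such wells were treated with simulated pairs in the closing section. The groups lie on 1 plate in blocks of adjoining plate lines, so group and plate position go together. Kept cells of a group held 46165993 (WT basal), 71077421 (WT luminal), 58980064 (ablated basal), 95990962 (ablated hybrid) and 86978845 (ablated luminal) reads in genes together, which gives a floor of 3 reads at 0.0650, 0.0422, 0.0509, 0.0313 and 0.0345 CPM.

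Levels were reads summed over kept cells divided by all their reads in genes and scaled to CPM, with exact Poisson 95% intervals, and log2 ratios were taken after adding 10 CPM. A gene was measured with a mean of at least 5 CPM over the 5 groups, which 11106 genes reached. Shares of cells were counted after thinning every cell at random to 100000 reads, with a gene detected at 5 reads, and carry exact Clopper-Pearson 95% intervals. Where 0 cells detected a gene, 3 cells of the group set the upper limit. Lineage genes were those differing 4-fold or more between the WT groups under the detection rule for named genes, 294 higher in luminal and 154 higher in basal cells. A cell's lineage position was the mean log2(CPM + 10) over the former minus that over the latter, and medians carry order-statistic intervals over cells. Each gene list was summarised by the median log2 ratio of its measured members, and placed among 10000 random lists of the same size matched in 20 abundance classes, as a description.

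Genes were named by a rule fixed before the data were examined. In each comparison it took the 10 largest and 10 smallest log2 ratios among genes with an official symbol, ribosomal and mitochondrial genes excepted. These needed at least 50 CPM and detection in at least 25% of cells in the higher group, and a share of detecting cells at least 20 points above the lower group. For hybrid cells it added the 10 genes highest over both ablated groups with shares at least 10 points above each. It also took keratin, lineage and sort genes set in advance and up to 4 members of each list with the largest ratios. The 24 lists were basal myoepithelial, luminal keratin and junction, hormone-responsive luminal, alveolar luminal, sorting antigens, transgenes, Notch pathway, Wnt pathway, EGFR pathway, TNF and NF-kB response, interferon response, cell cycle, p53 response, mesenchymal genes, progenitor-associated genes, laminin and hemidesmosome, dissociation and immediate early genes, and markers of immune, endothelial, fibroblast, pericyte, adipocyte, erythroid and skin keratinocyte cells.

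The 5 comparisons were WT luminal against WT basal, ablated basal against WT basal, ablated luminal against WT luminal, ablated hybrid against ablated basal and ablated hybrid against ablated luminal. No test between groups was run, since each group counts as 1 sample. Alternatives changed 1 choice at a time, namely the read minimum (50000 or 200000), the mitochondrial limit, the gene minimum (2000), equal weight per cell, median-of-ratios and TMM scaling, 1 CPM added in place of 10, and removal of the cell holding most reads of a gene. Further alternatives were the libraries of many cells, no abundance filter on list members, lineage genes at 8-fold or fixed lists in their place, detection at 1 or 20 reads, and no thinning. Subtraction of reads found in negative control wells was added after seeing the data.

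The steps were tested on simulated counts of 14123 genes with the depth of the real cells. With WT luminal made different from WT basal, all 100 genes made 4-fold different and all 100 made 8-fold different had the right direction, with median log2 ratios of 1.87 and 2.86 where 2.00 and 3.00 had been made. The lineage rule found 116 genes, 0 of them made alike, and 86 of the 100 genes made 8-fold different. Hybrid cells made to lie at 0.5 between both types on the log scale, not as mixes of cells, were placed at 0.50 and 0.51. A list made 2-fold different had a median of 1.08. Where no difference was made, all 19 lists lay within the central 95% of random lists, and the largest median was 0.22 in size. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors.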

Results

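RNA from single epithelial cells of the mouse mammary gland was sequenced with the full-length Smart-seq2 method in 384 wells. The cells had been sorted for the Tomato label, for CD29 (Itgb1) and EpCAM (Epcam), and against CD140a (Pdgfra), CD45 (Ptprc) and CD31 (Pecam1). Wild-type (WT) glands gave 50 basal and 50 luminal wells. Glands taken 1 week after an intraductal injection of 0.2 mg doxycycline, given to ablate luminal cells, gave 91 basal, 92 hybrid and 91 luminal wells. The extent of ablation was not measured here. The labels record no injection or doxycycline for WT glands. Ablation, injection, doxycycline and animal therefore cannot be told apart in comparisons of ablated with WT groups. The hybrid group is a group of the labels. Of these wells 319 were kept, namely 44 WT basal, 43 WT luminal, 71 ablated basal, 85 ablated hybrid and 76 ablated luminal cells. Kept cells held 118310 to 3835005 reads in genes, with group medians of 978494, 1372883, 677373, 1078728 and 1085297 reads in the same order. The remaining wells were 5 libraries of many cells, 1 per group, and 5 negative control wells.

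No animal is named for any cell, so every group counted as 1 sample without replicates, no test was run, and differences were not set against a spread between animals. Levels are reads summed over the cells of a group, in counts-per-million (CPM) of all gene reads, and log2 ratios were taken after adding 10 CPM to each side. A gene counted as detected in a cell at 5 or more reads after each cell was thinned to 100000 reads. Exact Poisson intervals of the levels were at most 3.92% wide on either side for named genes at 50 CPM or more. These Poisson intervals are too narrow even for counting error, because reads without molecular identifiers are not independent molecules, and they leave out the spread between cells. The exact Clopper-Pearson 95% intervals of shares cover the sampling of cells within a group only. Neither kind covers a spread between animals. Negative wells held a mean of 18.8 reads of Krt14, 27.2 of Acta2, 90.4 of Krt18 and 114 of Csn3 per well. A level that rests on a similar number of reads per cell can therefore be background in whole or in part, and folds over such a group are limited by it.

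The first comparison, WT luminal against WT basal cells, asked how far apart both lineages stood without ablation. Luminal cells carried the simple-epithelium keratins, tight-junction genes and milk-protein genes, and basal cells carried the contractile and stratified-type keratin program. Krt14 (ENSMUSG00000045545.8, GRCm38 chromosome 11, 100203162 to 100207548), a basal keratin, stood at 7154 CPM in basal and 35.4 CPM in luminal cells. It was detected in 88.6% (75.4 to 96.2) of basal and 6.98% (1.46 to 19.1) of luminal cells. Acta2 (ENSMUSG00000035783.8, chromosome 19, 34241090 to 34255590), the smooth-muscle actin of myoepithelium, was 148-fold higher in basal cells. Krt5 (ENSMUSG00000061527.6, chromosome 15, 101707070 to 101712898), the partner of Krt14, stood at 388 CPM in basal cells and was detected in 0 of 43 luminal cells, which allows a share of up to 6.98% of cells at the detection minimum. Trp63 (ENSMUSG00000022510.14, chromosome 16, 25683763 to 25892102), a basal transcription factor, was detected in 29.5% (16.8 to 45.2) of basal cells and likewise in 0 of 43 luminal cells. Krt18 (ENSMUSG00000023043.6, chromosome 15, 102028180 to 102032027) was 28.7-fold and Krt8 (ENSMUSG00000049382.9, chromosome 15, 101996698 to 102004482) 8.33-fold higher in luminal cells.

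Among the genes with the largest ratios, the secreted phosphoprotein Spp1 stood at 20123 CPM in luminal and 44.4 CPM in basal cells. The milk caseins Csn3, Csn1s1 and Csn2 had log2 ratios of 7.96, 7.93 and 6.57 towards luminal cells. The surface protein Ly6d, the plasma protein haptoglobin (Hp), the mucin-like Fcgbp, the claudin Cldn4, the keratin Krt19 and clusterin (Clu) followed at 7.47, 7.28, 7.06, 6.97, 6.93 and 6.81. On the basal side, the chemokine Cxcl14, the activin binder Fst, the sodium channel Scn7a, tropomyosin Tpm2 and the matrix protein Sparc had log2 ratios of −7.23, −7.15, −6.75, −6.29 and −6.22. The myosin light chain Myl9, the synuclein Sncg and the protease inhibitor Slpi followed at −6.14, −6.06 and −5.90. Without the cell holding most reads of the gene in each group, ratios were −8.32 for Krt14, 7.67 for Krt19, 7.42 for Clu and −6.91 for Tpm2. All 20 of these most different genes, Krt14 and Acta2 included, had the same sign in the libraries of many cells. Esr1 (ENSMUSG00000019768.16, chromosome 10, 4611593 to 5005614), the estrogen receptor, stood at 85.3 CPM in luminal and 86.9 CPM in basal cells. Elf5 (ENSMUSG00000027186.14, chromosome 2, 103411688 to 103450989), an alveolar transcription factor, stood at 111 and 0.282 CPM.

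Gene lists gave the same division. The basal myoepithelial list had a median log2 ratio of −5.24, with all 18 members below 0, and the luminal keratin and junction list a median of 4.80, with all 15 members above 0. The alveolar list had a median of 4.38 with 16 of 17 members above 0. The hormone-responsive list had a median of 3.69 with 10 of 11 above 0, led by Ly6a, Fxyd2 and Prlr, and of 1.98 without the cell holding most reads of each gene. The laminin and hemidesmosome list lay at −2.20 with all 13 members below 0, among them Col17a1 and Lamb3. Wnt pathway genes lay at −1.63 with 15 of 18 below 0, Sfrp1 and Lgr5 among them, and at −1.02 without the top cell. Progenitor-associated genes lay at −1.11, with Id4 lower in luminal cells, and mesenchymal genes at −3.29, with Vim and Thbs1 lower. Interferon response genes lay at 1.49, with Bst2 higher in luminal cells, and Irf7 higher too but opposite in sign in the libraries of many cells, and TNF and NF-kB response genes at 0.98, with Tnf higher and Icam1 lower. Lists without a clear lean were Notch pathway at −0.12, p53 response at −0.26, cell cycle at 0.00 and EGFR pathway at 0.03, the last of which turned to −0.02 under median-of-ratios scaling. The dissociation and immediate early list lay at −0.75, with Egr1 and Btg2 lower in luminal cells.

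Levels of the sort genes were taken in all groups. Epcam (ENSMUSG00000045394.8, chromosome 17, 87635979 to 87651129), which was used in the sort, stood at 3269 CPM in WT luminal, 766 in WT basal, 338 in ablated basal, 1958 in ablated hybrid and 2821 CPM in ablated luminal cells. Itgb1 (ENSMUSG00000025809.15, chromosome 8, 128685654 to 128733200), also used in the sort, stood at 186, 324, 478, 273 and 251 CPM in that order. It did not follow its gate clearly, as it was detected in 53.5% of WT luminal and 45.5% of WT basal cells and its ratio between them turned in the libraries of many cells. The sorting antigens list, which also holds Cd24a, had medians of 0.10, 0.31, 0.10, −0.21 and −0.20 in the 5 comparisons with 4 of 6 members measured, and the value of 0.10 for luminal cells after and without ablation turned to −0.13 with TMM scaling. Pdgfra, the gene of the excluded CD140a, was detected in 4.55% of WT basal and 8.45% of ablated basal cells.

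**Figure D1:**
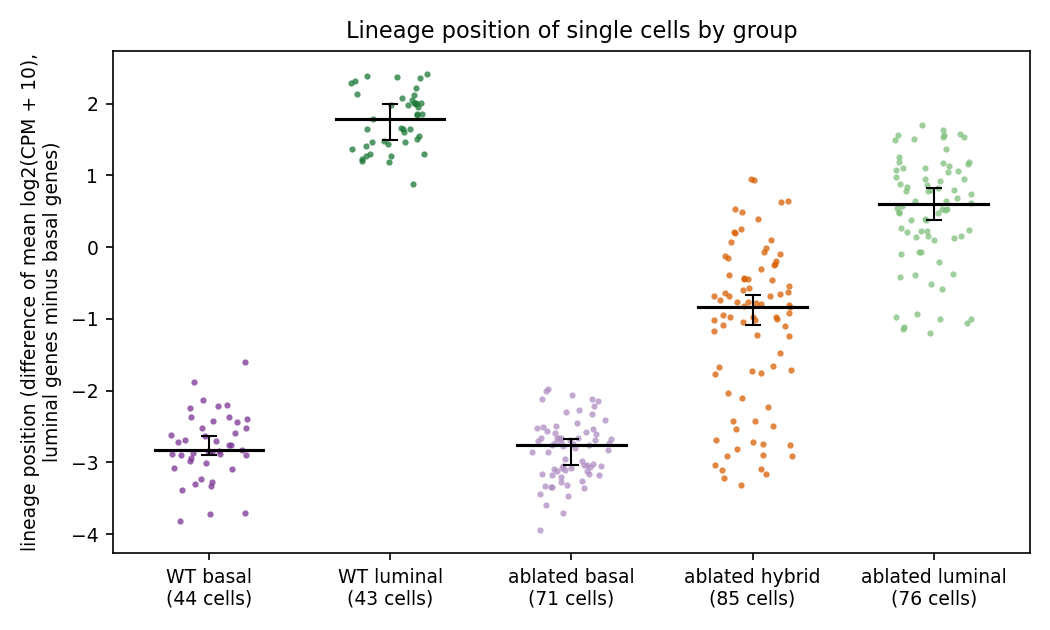
Lineage position of each kept cell by group, as the mean log2(CPM + 10) of genes higher in WT luminal cells minus that of genes higher in WT basal cells. Points are cells, long bars medians and whiskers 95% order-statistic intervals; ablated hybrid cells had a median of −0.83, between −2.76 for ablated basal and 0.60 for ablated luminal cells.

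The second comparison asked whether basal-gated cells differed after ablation of their luminal neighbours, from which injection and doxycycline could not be separated. They had higher levels of contractile genes such as Acta2 and Cnn1, and a lineage position close to that of WT basal cells with the main lineage genes but lower with fixed lists, at −2.65 against −1.45. Single matrix genes differed both ways, Fmod and Sparc being higher and Thbs1 and Ccn2 lower, and the laminin and hemidesmosome and the mesenchymal lists lay near 0. The median lineage position was −2.76 (−3.04 to −2.68) in ablated and −2.83 (−2.89 to −2.63) in WT basal cells, and all 71 ablated basal cells lay in the range of WT basal cells or below it. Krt14 stood at 7189 and 7154 CPM in ablated and WT basal cells, a log2 ratio of 0.01 that was −0.13 with TMM scaling. Acta2 was 3.06-fold higher, at 16591 CPM in ablated basal cells, and the matrix protein Sparc stood at 6605 against 1340 CPM. The largest ratios towards ablated basal cells were those of the collagen-binding fibromodulin (Fmod) at 5.25, the Wnt and BMP antagonist Sostdc1 at 4.66, the EMI-domain gene Emid1 at 4.37 and the glutathione enzyme Ggt1 at 3.97. The actin Actg2, whose sequence is close to that of Acta2, the calcification inhibitor Mgp, the growth-factor binder Igfbp5 and the proteoglycan Vcan followed at 3.90, 3.83, 3.57 and 3.36. Fmod was detected in 39.4% (28 to 51.7) of ablated basal and 0 of 44 WT basal cells, which allows up to 6.82%. Without the cell holding most of its reads the ratio of Emid1 was 5.15. Of 4 measured fibroblast markers 3 were higher in the same comparison. Their list median was 0.88 (−0.94 to 1.85 over genes), and 1.77 without the top cells. Dcn stood at 1806 against 813 CPM and Col1a2 at 61.3 against 9.83 CPM, but Col3a1 was lower, at 5.95 against 20.6 CPM.

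Genes lower in ablated basal cells included the synuclein Sncg at a log2 ratio of −2.55, the TWEAK receptor Tnfrsf12a at −2.43, Scn7a at −2.34, the transcription factor Cebpb at −2.18 and the YAP target Ccn2 at −2.09. Pdk4, a metabolic kinase, and Slpi followed at −1.64 and −1.39. Of the 20 most different genes 15 had the same sign in the libraries of many cells. The exceptions were Mtf2 and Ppp2r5c, with single-cell ratios of 3.41 and 3.33, and Crybb3, Acsl4 and Tpbg, with −1.95, −1.47 and −1.37. Across the 5099 genes at 50 CPM or more in a group, the single-cell and many-cell log2 ratios had a Pearson correlation of 0.16, over genes that are not independent replicates. The basal myoepithelial list had a median of 0.63, with 14 of 18 members above 0, among them Cnn1 and Tagln, and lay above 9990 of 10000 random lists of matched abundance. The remaining lineage lists lay near 0, with 0.05 for the luminal keratin and junction list, which turned to −0.01 with TMM scaling, 0.02 for the hormone-responsive and −0.07 for the alveolar list. In the latter, Plet1 and Plin2 were lower in ablated basal cells. The medians were 0.20 for Wnt pathway genes, with Lgr6 and Nkd1 higher, 0.30 for Notch, 0.13 for EGFR, 0.01 for TNF and NF-kB, −0.01 for interferon and 0.01 for cell cycle genes. They were −0.29 for p53 response, −0.00 for mesenchymal, 0.00 for progenitor-associated and −0.03 for laminin and hemidesmosome genes, the last with Col4a1 and Col4a2 higher and Plec lower. The dissociation and immediate early list lay at −0.40, with Atf3 and Btg2 lower.

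The third comparison, ablated luminal against WT luminal cells, asked what set the luminal-gated cells found after ablation apart from ordinary luminal cells. As a group they had luminal keratins near the WT luminal level, carried basal keratins that WT luminal cells nearly lacked, and had much less milk-protein transcript. Csn1s1 varied widely between WT luminal cells, with a median of 163 CPM and a 75th percentile of 12740 CPM. It was detected in 69.8% of WT luminal and 9.21% of ablated luminal cells. Fewer casein-rich cells and less transcript per cell were not told apart. Other secreted products went both ways, with Spp1 and Lcn2 lower and Slpi and Areg higher. The origin of these cells was not tested. The median log2 ratio over the 11106 measured genes was 0.21 here, and 0.01 with TMM scaling. Without the cell with most reads of each gene it was 0.38. Ratios in each setting should be read against the median of that setting. Krt8 stood at 4269 against 3746 CPM, a ratio of 0.19 that was −0.11 with TMM scaling, and Krt18 at 6861 against 8343 CPM. Krt14 stood at 3920 against 35.4 CPM, a log2 ratio of 6.44 and of 7.38 without the cell with most of its reads, and was detected in 63.2% (51.3 to 73.9) against 6.98% (1.46 to 19.1) of cells. Its cells varied widely, with a median of 283 CPM and a 90th percentile of 12145 CPM. In the ablated luminal library of many cells Krt14 reached only 165 CPM. Krt5 stood at 288 CPM and was detected in 23.7% (14.7 to 34.8) of ablated luminal cells, and Trp63 at 49.1 CPM in 15.8% (8.43 to 26).

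Other genes at the top towards ablated luminal cells were Slpi at a log2 ratio of 5.06, the lactate-transporter chaperone Emb at 4.86, Emid1 at 4.64, the progenitor-type keratin Krt15 at 4.56 and Sparc at 4.33. Krt6a, a keratin of wounded epithelium whose reads may be shared with its close copy Krt6b, the water channel Aqp3, Krt17 and the connexin Gja1 followed at 4.24, 4.18, 4.17 and 4.12. Krt17 reached 4.90 without the cell with most of its reads. On the other side stood Csn1s1 at −5.76, or −6.53 without that cell, Csn1s2a at −4.19, Csn3 at −3.96, the chitinase-like Chil1 at −3.94 and Spp1 at −3.31. The iron-binding proteins Lcn2 and transferrin (Trf) followed at −3.30 and −3.15, and the osteocalcin-like Bglap3, whose reads may be shared with close copies, at −3.22. Spp1 was still at 2017 CPM in ablated luminal cells. Of the 20 most different genes 17 had the same sign in the libraries of many cells, and Krt15, Ccn5 and Ceacam10 had the opposite sign. Ccn5 and Ceacam10 had single-cell ratios of −3.74 and −3.42. Krt5 and Acta2 also turned, Acta2 having a single-cell ratio of 2.67, so basal transcripts of these genes in luminal-gated cells rested on the single cells alone.

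The basal myoepithelial list had a median of 1.83 with 17 of 18 members above 0, above all 10000 random lists, but of 0.00 in the libraries of many cells. With 1 CPM added it was 3.20. The luminal keratin and junction list lay at −0.15, with Muc1 lower. The alveolar list lay at −2.06 with 14 of 17 members below 0, below all random lists, and the hormone-responsive list at 0.38, with Areg and Tph1 higher and Prlr lower. Cell cycle genes had a median of 1.73 with all 17 members above 0, among them Cdk1 and Rrm2. In the libraries of many cells the list and both genes stood at 0.00. With 10 CPM added, few or no reads of a gene in both libraries also give 0.00, so a value of 0.00 does not show equal levels. Wnt pathway genes lay at 0.87, with Lgr5 and Znrf3 higher and Wnt5b lower, and laminin and hemidesmosome genes at 0.86, all 13 members above 0. Progenitor-associated genes lay at 0.86, all 13 above 0, with Sox9 among them, mesenchymal genes at 1.17, with Vim higher, and EGFR pathway genes at 0.66, with Epgn higher. In the libraries of many cells the Wnt pathway and laminin and hemidesmosome medians were nearer to 0, and the progenitor-associated median was 0.00. Interferon response genes lay at −1.18 with 10 of 12 below 0, with Ifi44 lower, and TNF and NF-kB response genes at −0.47, with Icam1 higher. Both the interferon and the TNF medians, and single members such as Usp18, Cxcl2 and Gbp2, had the opposite sign in the libraries of many cells. The p53 response list lay at 0.14, the dissociation list at −0.24, and the Notch list at 0.23, which was −0.04 with TMM scaling.

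The comparisons of hybrid cells with ablated basal and with ablated luminal cells asked how they stood between the basal and luminal cells of the ablated glands. As a group, hybrid cells carried contractile basal transcripts together with luminal keratins and claudins, and a part of them carried caseins. Their median lineage position was −0.83 (−1.08 to −0.67), and 56 of 85 cells, 65.9% (54.8 to 75.8), lay between the ranges of WT basal and WT luminal cells. Another 27 cells lay in the WT basal range and 2 in the WT luminal range. Of the ablated luminal cells, 51 of 76, 67.1% (55.4 to 77.5), also lay between both ranges. The lineage genes were picked for their difference between these same WT cells. This sets the WT ranges apart by construction, so cells of other groups tend to fall between them. With fixed lists the medians were −1.45 for WT basal, 1.08 for hybrid, 4.71 for ablated luminal and 5.13 for WT luminal cells. Basal and luminal keratins, meaning Krt14 or Krt5 together with Krt8 or Krt18, were detected in 83 of 85 hybrid cells, 97.6% (91.8 to 99.7). The same held for 76.1% (64.5 to 85.4) of ablated basal, 63.2% (51.3 to 73.9) of ablated luminal, 81.8% (67.3 to 91.8) of WT basal and 6.98% (1.46 to 19.1) of WT luminal cells. Keratin pairs thus separated hybrid cells poorly from basal cells, in which Krt8 reached 450 CPM without ablation. Acta2 together with Krt19, each at 20 or more reads, was more selective, with 68.2% (57.2 to 77.9) of hybrid cells against 1.41% (0.0357 to 7.60) of ablated basal and 15.8% (8.43 to 26) of ablated luminal cells. Simulated pairs of an ablated basal and an ablated luminal cell gave 82.6% for Acta2 with Krt19 and 99.8% for the keratins. Pairs with a WT luminal cell gave 89.4% and 98.4%. Both shares for Acta2 with Krt19 lay above the hybrid interval of 57.2 to 77.9. All pairs were made from equal reads of both cells, so the shares of pairs with unequal reads are not known. The keratin shares were too near 100% to tell pairs from hybrid cells. Pairs were therefore not excluded.

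**Figure D2:**
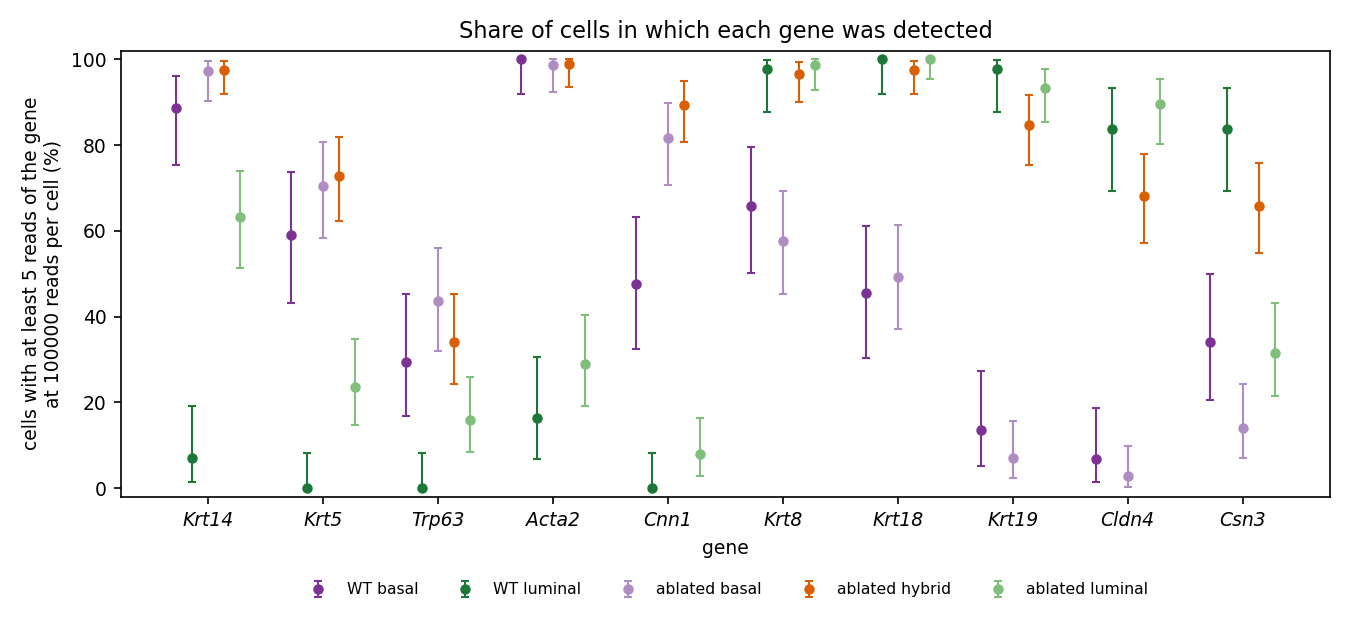
Share of cells with at least 5 reads of each gene at 100000 reads per cell, by group, with 95% Clopper-Pearson intervals as bars. Ablated hybrid cells had high shares both for Acta2 (98.8%) and for Krt19 (84.7%).

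Against ablated basal cells, hybrid cells had Krt19 at 2670 against 12.2 CPM, the endotoxin co-receptor Cd14 at 1454 against 3.02 CPM and the whey-acidic-type protein Wfdc18 at 1462 against 4.70 CPM. Csn3, Csn1s1, Clu, Cldn7, Spp1, the EGFR ligand Areg and Cldn4 had log2 ratios of 6.08, 6.01, 5.99, 5.53, 5.48, 5.42 and 5.39. Krt18 was 15.4-fold, Krt8 6.45-fold and Epcam 5.80-fold higher in hybrid cells. The 6 genes that met the naming rule on the other side were the plasminogen activator Plat at −2.37, the complement gene C4b at −2.29, Apoc1 at −1.73, the Wnt receptor Fzd7 at −1.52, Tshz2 at −1.38 and Tagln at −1.22. Krt14, Krt5 and Acta2 were lower in hybrid cells by similar factors, with log2 ratios of −0.95, −0.95 and −1.03, and Trp63 stood at −2.23. The median log2 ratio over measured genes was 0.14, 0.01 with TMM scaling and 0.36 without the cell with most reads of each gene. Of the 16 most different genes 15 had the same sign in the libraries of many cells, Fzd7 being the exception, and the sign of Trp63 also turned there.

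The luminal keratin and junction list had a median of 3.71 with 14 of 15 members above 0, and the alveolar list one of 3.21 with all 17 above 0. The hormone-responsive list had a median of 2.30 with 10 of 11 above 0, which was 1.53 without the top cell of each gene, with Cited1 and Prlr higher. The basal myoepithelial list lay at −0.95 with 16 of 18 below 0. Interferon response genes lay at 1.32 with 11 of 12 above 0, among them Rtp4. Cell cycle genes lay at 1.41 with all 17 above 0. In the libraries of many cells the cell cycle median was 0.00, which few or no reads in both libraries would also give. EGFR pathway genes lay at 0.71, with Epgn higher and Spry2 lower, and TNF and NF-kB response genes at 0.41, with Tnfaip2 and Relb higher. Gbp2 was higher and Cxcl1 lower in the single cells, and both turned in the libraries of many cells. Wnt pathway genes lay at −0.52, with Lgr5 and Rnf43 lower, laminin and hemidesmosome genes at −0.70, with Dst and Lamb3 lower, and the dissociation list at −0.45, with Fos and Egr1 lower. Notch genes lay at −0.32, progenitor-associated genes at −0.36, p53 response genes at −0.17 and mesenchymal genes at −0.08.

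Against ablated luminal cells, hybrid cells were set apart by the contractile program. Myl9 was 43.2-fold, Acta2 28.2-fold, Cnn1 22.7-fold, the myosin heavy chain Myh11 23.0-fold and its kinase Mylk 16.9-fold higher. Actg2, the cytokine Il17b, the basement-membrane collagen Col4a2 and Olfml3 had log2 ratios of 4.57, 4.25, 3.73 and 3.65. Csn1s1 was also higher, at 3.75, or 4.34 without the cell with most of its reads. Krt14 stood at 3714 and 3920 CPM in hybrid and ablated luminal cells, a log2 ratio of −0.08, but was detected in 97.6% (91.8 to 99.7) against 63.2% (51.3 to 73.9) of cells. In the libraries of many cells Krt14 stood at 992 against 165 CPM. Higher in ablated luminal cells were Krt6a at −4.33, the gluconeogenic enzyme Fbp1 at −3.74, Ly6d at −3.52, the chemokine Cxcl17 at −3.29 and the surface protein Ly6a at −2.97. Aqp3, the glutathione reductase Gsr, Wfdc2, the progesterone receptor Pgr and Pir followed at −2.86, −2.69, −2.65, −2.47 and −2.43. All 20 of these genes had the same sign in the libraries of many cells.

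The basal myoepithelial list had a median of 2.60 with 17 of 18 members above 0, and the luminal keratin and junction list lay at −0.61 with 14 of 15 below 0, among them Krt7 and Krt19. The hormone-responsive list lay at −1.29 with all 11 members below 0, Fxyd2 and Tph1 among them, and the alveolar list at 0.46, with Csn2 higher and Ltf lower. Wnt pathway genes lay at 0.63, with Wnt10a and Lgr6 higher, laminin and hemidesmosome genes at 0.56, with Col4a1 and Lama3 higher, and mesenchymal genes at 0.74, with Sparc higher. Interferon response genes lay at 0.57, with Iigp1 higher, though without a lean in the libraries of many cells, where Cxcl10 and Gbp2 turned, TNF and NF-kB response genes at 0.21, Notch genes at 0.03, and the dissociation list at 0.02, which was −0.01 under median-of-ratios scaling. The medians were −0.31 for cell cycle, −0.27 for EGFR, −0.11 for p53 response and −0.21 for progenitor-associated genes.

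**Figure D3:**
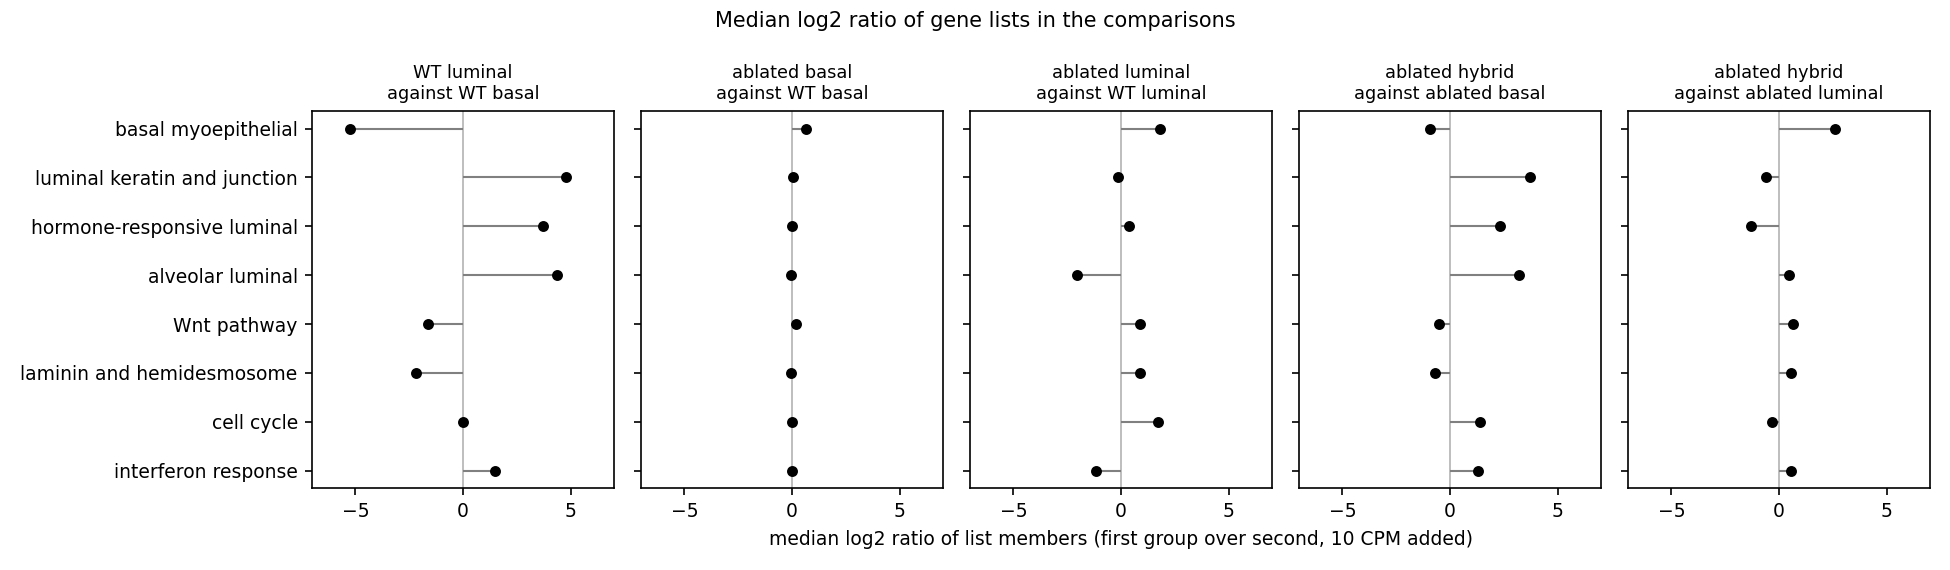
Median log2 ratio of the members of 8 gene lists in each of the 5 comparisons, first group over second, with 10 CPM added to each side. Points are medians and lines run from 0; the basal myoepithelial list lay at −0.95 and 2.60 for ablated hybrid cells against ablated basal and ablated luminal cells.

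Placed gene by gene between ablated basal cells at 0 and ablated luminal cells at 1, hybrid cells had a median of 0.83 (0.78 to 0.88) over 200 genes higher in WT luminal cells. Over 125 genes higher in WT basal cells the median was 0.43 (0.38 to 0.48), where the intervals run over genes. On the log scale used, an even mix of RNA of both groups also lies nearer to the group richer in a gene. These medians therefore do not tell an intermediate state from pairs. A few genes were higher in hybrid cells than in both neighbours, but they were picked and measured in the same cells, which favours large ratios. Hybrid-high genes picked in odd-numbered cells had a median log2 ratio of −0.33 over the richest other group in even-numbered cells. Of the genes named here, Csn1s1 and Csn3 stood higher still in WT luminal cells, at 8152 and 11416 CPM against 2007 and 2668 CPM in hybrid cells. Csn1s1 had ratios of 6.01 and 3.75 over ablated basal and ablated luminal cells, and Csn3 had 6.08 and 1.87, although the second of these turned in the libraries of many cells. Lbp, the lipopolysaccharide binder, had 3.01 and 1.58, the phospholipase Plb1 4.21 and 1.52, the potassium channel Kcnh1 1.40 and 2.20, and the nucleoside transporter Slc28a3 4.18 and 1.36. Without the cell with most reads these were 3.95 over ablated basal cells for Lbp and 2.48 over ablated luminal cells for Slc28a3. Asb6 had ratios of 1.65, or 2.39 without the top cell, and 1.35, the latter opposite in sign in the libraries of many cells. The class I genes H2-Q7, H2-Q4 and H2-Q6 had 3.08, 1.55 and 1.68 over ablated basal cells, but these genes are close copies of each other, so their single values are uncertain.

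Marker lists of other cell types were mostly low. Of 12 immune cell markers 4 were measured, with medians of 0.03, 0.81, 0.90, 0.70 and 0.63 in the 5 comparisons in the order given above. Cd74, the most abundant of them in ablated cells, was detected in 22.4% of hybrid cells and in 0 of 44 WT basal cells, which allows up to 6.82%. Of 8 fibroblast markers 4 were measured, with medians of −1.30, 0.88, −0.15, −1.25 and 1.47, or −0.24 and 1.77 for the first and second without the top cells. Their most abundant member Dcn was detected in 63.5% of hybrid, 52.1% of ablated basal, 38.6% of WT basal, 16.3% of WT luminal and 5.26% of ablated luminal cells. Of 5 erythroid markers 4 were measured, with medians of 0.03, 0.00 and 0.05 in the comparisons without hybrid cells and of 3.41 and 3.34 for hybrid against ablated basal and ablated luminal cells. The latter were 0.24 and 0.08 without the top cells. Of 6 pericyte and 8 skin keratinocyte markers 2 each were measured, and of 9 endothelial and 6 adipocyte markers 0, so no medians were formed. Their summed levels were at most 37.3 CPM for pericyte, 24.7 CPM for skin keratinocyte, 15.3 CPM for endothelial and 6.51 CPM for adipocyte markers in any group. Transgenes, Tomato included, were not analysed here.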

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

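Tests of reads leaking between wells, of basal RNA among luminal-gated cells and of the place on the plate were chosen after the result was seen, and the other tests before. The negative control wells, which no comparison used, were singled out because they held reads well above the 3 counts that bound a count of 0. Their median was 12496 reads in genes, with a range of 7930 to 13572 and 3273 to 4355 genes per well. That median is 1.19% of the median kept cell. Across genes, their summed reads had a Spearman correlation of 0.75 with those of the kept cells, over genes that are not independent replicates. No single well stood apart, with a gap of 0.353 of the range against Dixon's limit of 0.71.

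Hybrid cells held basal and luminal transcripts together, and 3 technical explanations were tested. Reads leaking at the level of the negative wells were excluded as the whole cause. After the highest count of any negative well was subtracted, 91.8% of hybrid cells (83.8 to 96.6) kept both keratin classes. The negative wells lie in plate line A and the hybrid wells in lines M to P, so leaking between neighbouring wells there was not measured. A mixture of separate basal and luminal cells in the hybrid group was excluded as the whole cause as well, though not in part of the wells, as 27 of 85 cells lay in the WT basal range. Acta2 and Krt19 were found together in 68.2% of hybrid cells (57.2 to 77.9), above ablated basal (1.41%) and ablated luminal cells (15.8%). Wells with a pair of cells stayed open. A pair cannot exceed its richer member, so genes picked as highest in 43 odd-numbered hybrid cells were measured in the 42 even-numbered cells. These 63 genes had a median log2 ratio over the richest other group of −0.33 (−0.75 to −0.15 over genes), with 17 above 0. Genes without any difference also give negative ratios over the highest of several groups, and an intermediate state need not exceed either type. The test therefore could not tell pairs from intermediate cells.

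Pairs simulated from ablated basal and ablated luminal cells had a median lineage position of −1.39, and pairs with WT luminal cells one of −0.79, against −0.85 for hybrid cells treated alike. Their median numbers of genes were 4960 and 3993 against 4616, and Acta2 with Krt19 appeared in 82.6% and 89.4% of them, and both keratin classes in 99.8% and 98.4%, against 97.6% (91.8 to 99.7) of hybrid cells. The positions and gene numbers of both kinds of pairs surround those of the hybrid cells, while both shares with Acta2 and Krt19 lie above the hybrid interval of 57.2 to 77.9. As a simulation these values exclude neither pairs in part of the wells nor a true intermediate state. The held-out median of −0.33 does not decide between them. Hybrid wells may hold intermediate cells, pairs, separate basal or luminal cells in part of the wells, or a mixture of these. Ablation as a biological cause was not tested.

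Krt14 in ablated luminal cells was the next pattern. Negative wells gave 0.419% of its reads, so leaking at the level of those wells was excluded as its cause. The negative wells lie in plate line A and the ablated luminal wells in lines I to M, so leaking between neighbouring wells there was not measured. Basal cells or their RNA would bring the other basal transcripts along, but the 17 other members of the basal myoepithelial list stood at a median of 4.64% of their ablated basal level (2.25 to 13.9), against 54.5% for Krt14. Krt17, Col17a1 and Krt5 stood at 43.8%, 39.6% and 32.6%, and Acta2 at 1.73%. Basal RNA as the whole source was therefore excluded. A basal keratin program without the contractile one may mark these cells, as a hypothesis found and tested on the same data. Against WT luminal cells, the libraries of many cells gave log2 ratios of 1.55 for Krt14, 2.03 for Krt17 and 2.72 for Krt6a. Krt5 and Krt15 turned there, to −0.22 and −0.02. In the ablated luminal library of many cells Krt14 stood at 165 CPM against 3920 CPM in single cells, for which no cause was tested.

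Ablated luminal cells had more genes per cell than WT luminal cells at equal depth, with medians of 4330 and 2918 at 100000 reads, a ratio of 1.48. Without the 100 most abundant genes, at 50000 reads, the ratio was again 1.48, so a few genes taking most of the counts were excluded as its cause. Place on the plate and group cannot be told apart, because 0 plate lines held wells of both groups. RNA content could not be measured, as spike-in reads were nearly absent, and the ablation stays open as an untested biological cause.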

How the results depend on the processing

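The subtraction of negative control reads was chosen after the data were seen, and the other alternatives before. The basal myoepithelial and the luminal keratin and junction medians in the 5 comparisons gave 115 of 120 values within their intervals over genes. Only 2 of their medians lost their direction, the basal list in the libraries of many cells and the luminal list, at 0.05 for ablated against WT basal cells, with either scaling. Other list medians gave 964 of 1020 values within their intervals, 51 moved and 5 reversed. Ratios of the most different and the preset genes gave 892 unmoved values, 842 moved beyond counting error and 15 of at least 1 in size reversed. The cause was not tested unless stated.

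Ratios of at least 1 in size of these genes, and list medians whose intervals over genes left out 0, reversed in the libraries of many cells only. Smaller ratios also turned in other settings, for ablated against WT luminal cells Krt8 from 0.19 to −0.11 and Esr1 from 0.14 to −0.12 with TMM scaling. For ablated against WT basal cells the libraries of many cells gave 0.53 for Acsl4, 0.81 for Crybb3, −0.96 for Krt5, −0.51 for Mtf2, −0.10 for Ppp2r5c, 0.71 for Tpbg and 0.07 for the alveolar list. For ablated against WT luminal cells they gave −1.25 for Acta2, 1.08 for Ccn5, 0.05 for Ceacam10, −0.02 for Krt15 and −0.22 for Krt5. The lists there stood at 0.62 for TNF and NF-kB response, 0.74 for interferon response, −0.50 for erythroid markers and 0.00 for the basal myoepithelial list. For hybrid against ablated basal cells they gave 0.03 for Fzd7, 0.10 for Trp63 and 0.02 for the Wnt list, and against ablated luminal cells −2.40 for Asb6 and −0.07 for Csn3. List members outside these counts turned there as well, Irf7 between the WT groups to −2.46, and Cxcl2 to 2.38, Fos to 1.84, Gbp2 to 1.86, Usp18 to 0.16 and Id4 to −0.02 for ablated against WT luminal cells. Hybrid cells had −1.74 for Gbp2 and 0.70 for Cxcl1 against ablated basal cells, and −0.91 for both Cxcl10 and Gbp2 against ablated luminal cells.

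With 1 CPM added, which stretches ratios of low genes by construction, the basal myoepithelial list stood at −7.22 between the WT groups and at 3.20 for ablated against WT luminal cells. For hybrid against ablated basal cells it was −0.89 with equal weight per cell and −1.20 with median-of-ratios scaling. Under the latter, hybrid cells had a position of 0.51 per WT basal gene, and one of 0.27 with fixed lists.

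Lineage positions depend on the genes used by construction. With 1 CPM added the medians were −4.50 for WT basal, 2.55 for WT luminal, −4.33 for ablated basal and −1.41 for hybrid cells. With lineage genes at 8-fold they were −2.90 for WT basal, 2.28 for WT luminal, −3.20 for ablated basal and 0.87 for ablated luminal cells. With fixed lists they were −1.45 for WT basal, 5.13 for WT luminal, −2.65 for ablated basal, 1.08 for hybrid, a change of sign, and 4.71 for ablated luminal cells. Hybrid cells lay between ablated basal and ablated luminal cells in each of these settings.

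Co-detection of keratins at 1 thinned read was 95.5% in WT basal, 58.1% in WT luminal, 97.2% in ablated basal, 100% in hybrid and 92.1% in ablated luminal cells. At 20 reads it was 47.7% in WT basal, 54.9% in ablated basal and 85.9% in hybrid cells. After subtraction of the highest negative control count it was 65.9% in WT basal and 60.6% in ablated basal cells. Of 1335 shares of cells detecting a gene 803 stayed within their binomial intervals.

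No paired analysis was possible because no animal is named. With 43 to 85 cells per group, a gene detected in 0 cells allows detection in up to 3.53% to 6.98% of cells, which sets no limit on cells with fewer than 5 thinned reads of it. The many-cell libraries, at Pearson correlations of 0.16 to 0.45 with pooled cells across genes, limit single ratios further, such as −0.07 for Csn3.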

Other observations

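The values in this part were chosen after the data were seen, and no test was run on them. Transcripts of mitosis marked cells of the ablated hybrid and luminal groups. At least 1 of 12 mitotic genes, among them Mki67 and Top2a, was detected in 29 of 85 hybrid cells, 34.1% (24.2 to 45.2), and in 18 of 76 ablated luminal cells, 23.7% (14.7 to 34.8). The same held for 4 of 71 ablated basal cells, 5.63% (1.56 to 13.8), and 1 of 43 WT luminal cells. It held for 0 of 44 WT basal cells, with an interval of up to 8.04%. At least 3 of these genes were found in 12 hybrid and 9 ablated luminal cells and in 0 cells of the other groups. In the libraries of many cells the cell cycle list stood at 0.00 for ablated against WT luminal and for hybrid against ablated basal cells. Few or no reads in both libraries also give 0.00, so these medians do not show equal levels. More genes were detected per cell at equal depth in the hybrid and ablated luminal groups, with medians of 4616 and 4330, against 2213 to 2918 in the other groups.

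Hemoglobin reads in the hybrid group came almost wholly from 1 cell. Replicate 5 held Hbb-bs at 98121 CPM and Hba-a1 at 42054 CPM, against at most 55.3 and 31.6 CPM in any other hybrid cell. Both genes have close copies, so the division of reads among the copies is uncertain.

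Krt15 and Krt6a split the ablated groups. Krt15 was detected in 58.8% (47.6 to 69.4) of hybrid, 33.8% (23.0 to 46) of ablated basal and 32.9% (22.5 to 44.6) of ablated luminal cells, against 4.55% (0.555 to 15.5) of WT basal cells. Krt6a was detected in 31.6% (21.4 to 43.3) of ablated luminal cells and in 1.18% (0.0298 to 6.38) of hybrid cells.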
